A study of Mus musculus with 18 samples.

How the data were processed

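CLEAR-CLIP was done on mouse keratinocytes grown in culture, 18 libraries in 2 sets. Set 1 held 6 control libraries (K14-Cre only) and 3 miR-200 DKO libraries. Set 2 held 3 uninduced controls (miR-200 inducible cells without doxycycline), 3 miR-200 DKO libraries and 3 libraries of inducible cells given 3 ug/ml doxycycline for 24 hours. Per the labels' protocols, cells received 300 mJ/cm2 of UV light at 254 nm, Argonaute 2 was precipitated after light RNase digestion, and miRNA and target were ligated on the beads. Per the submitters' processing notes cutadapt, Novoalign, bedtools and the mm10 genome were used, with no versions given. The deposited files hold another kind of unit than counts or signals, namely positions: each entry is 1 chimeric read with the mm10 position and strand of its target part, a 4-base barcode and the name of the ligated miRNA. No 2 entries of a file share position, strand, miRNA and barcode, so the authors' collapse of amplified copies is already in the files; how it was done is not given in the sources used here.

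Each group's libraries are pooled in 1 file with no library name, so each group was treated as 1 pooled sample. By the deposited read names, all pools of a set ran in 1 sequencing lane, and the sets ran on different flow cells, so that set and sequencing run coincide. The pools held 161692 (set 1 control), 48662 (set 1 DKO), 314071 (set 2 uninduced control), 210003 (set 2 DKO) and 419117 (set 2 induced) chimeric reads, 1153545 in all, with 1797 miRNA names. They lay on 117472, 37839, 258909, 181610 and 346032 distinct combinations of position, strand and miRNA. A floor of 3 reads corresponds to 0.00186%, 0.00616%, 0.000955%, 0.00143% and 0.000716% of a pool. Target parts had a median of 37 to 40 bases (20 to 124 over all pools). In set 1, 8.53% of control and 4.46% of DKO reads have marked names and shorter targets (median 22 bases); they were kept, and left out in an alternative.

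Shares of a miRNA are chimeric reads of that miRNA over all chimeric reads of the pool, with the exact Clopper-Pearson 95% interval. Ratios of shares have the conditional exact interval. A miRNA or target gene was counted as higher or lower where this interval excluded 1 and the compared pools held at least 20 reads; no test was made between groups. miR-200 target genes, sites, overlap, gene lists and target classes count distinct combinations of position, strand and miRNA, called chimeras; shares, ratios and target genes of other miRNAs count every read. A target was assigned to a RefSeq gene of the same build by the midpoint of its target part over whole gene spans, in the order mitochondrial, small structured RNA, miRNA gene, protein-coding, noncoding RNA, pseudogene or other; targets within several protein-coding genes, structured RNA and mitochondrial targets were counted but not named. Exons, strands of genes and genome sequence were not used here, so seed matches and UTR or coding classes were not analysed here. Sites are groups of overlapping miR-200 targets on 1 strand over the set 1 control, uninduced and induced pools. Coordinates count from 1 on mm10.

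The groups, comparisons, gene and miRNA lists, count minimums and rule for named genes were set before the data were examined; had libraries been named, tests between them were planned. Named miRNAs are the 5 family members, the 10 other miRNAs with the highest mean share over the 5 pools, and per direction the 5 largest ratios with at least 50 reads whose interval excludes 1 (for DKO in both sets the same way). Named target genes are the 20 with the highest mean share of miR-200 chimeras, the 3 leading members of each list with at least 5 chimeras, and for other miRNAs the 5 largest ratios per direction under the rule for miRNAs. Of the 13 gene lists, 1 was tested and is not reported; the others were EMT regulators and mesenchymal, commonly cited miR-200 targets, cell and focal adhesion, cell cycle, basal keratinocyte, differentiated keratinocyte, Wnt and hair follicle, small RNA machinery, fibroblast, melanocyte, immune and endothelial. The 15 miRNA lists were the miR-200 family, epidermal, let-7, miR-17-92, miR-183 cluster, miR-34, miR-29 and miR-30, miR-15 and miR-16, mesenchymal, muscle, blood, endothelial, neural, liver and embryonic. Gene lists were compared with Fisher's exact test on chimeras within a pool, adjusted by Benjamini-Hochberg at 0.05, and overlaps with 10000 seeded draws of genes weighted by the chimeras of other miRNAs.

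Alternatives were each position counted once or every read, other count minimums, the guide arm alone, totals without the most abundant miRNA or gene or without the miR-200 family, and targets without structured RNA. Alternatives added after the data were seen left out reads shared within the lane (same position, strand, miRNA and barcode in another pool of the set), marked read names, 9 miRNAs overrepresented in set 1 (miR-709, miR-706, miR-3470a, miR-3470b, miR-3473b, miR-7667-5p, miR-1195, miR-5099 and miR-6380) or the gene with the most miR-200 chimeras of each gene list, over the 3 pools or in each pool, counted the 9 among other miRNAs on sites and gene ends, or asked for at least a 2-fold ratio. The intervals were tested on simulated data of the same depth. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.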

Results

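Chimeric reads in which a miRNA was ligated to its target were compared in cultured mouse keratinocytes that kept the miR-200 family, lacked it (miR-200 double knockout, DKO) or carried a doxycycline-inducible form of it. The family (miR-200a, miR-200b, miR-200c, miR-141 and miR-429, known for keeping epithelial character) held 3.20% of chimeric reads in the set 1 control pool (95% counting interval 3.12 to 3.29) and 6.68% (6.59 to 6.76) in the set 2 uninduced control pool. In the DKO pools its share was 0.160% (0.127 to 0.200; 78 reads) in set 1 and 0.360% (0.334 to 0.386; 755 reads) in set 2, which is 20.0-fold lower (16.0 to 25.3) and 18.6-fold lower (17.3 to 20.0) than control. In the induced pool the share was 9.04% (8.95 to 9.13), 1.35 times that of the uninduced control (1.33 to 1.38). The files used here pool the libraries of each group, so intervals cover counting error alone and no test was made between groups. Of the DKO miR-200 reads, 67.9% (set 1) and 90.5% (set 2) were also present, with the same position and barcode, in another pool of the same lane; without such reads the DKO ratios to control were 0.0186 (0.0120 to 0.0275) and 0.00546 (0.00427 to 0.00688).

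The 5 members were all lower in both DKO pools. In set 2 the shares of DKO over control were 0.0883 for miR-429, 0.0841 for miR-200b, 0.0665 for miR-200a, 0.0455 for miR-200c and 0.0436 for miR-141, and in set 1 they lay between 0.0344 (miR-429, 0.00933 to 0.0889) and 0.0652 (miR-141, 0.0457 to 0.0901). Without reads shared within the lane, those of miR-200b, miR-200c, miR-141 and miR-429 lay between 0.00434 and 0.00808 in set 2 and between 0.00995 and 0.0281 in set 1. Induction moved the members unequally. The members of the miR-200b, miR-200a and miR-429 cluster held more than double the uninduced share. miR-200b went from 0.963% to 2.44% (ratio 2.54, 2.44 to 2.64), miR-429 from 0.405% to 0.917% (2.27, 2.13 to 2.42) and miR-200a from 0.265% to 0.578% (2.18, 2.02 to 2.36). The members of the other cluster stayed close to it, with miR-200c at 2.79% and 2.89% (1.04, 1.01 to 1.06) and miR-141 at 2.25% and 2.21% (0.980, 0.95 to 1.01). By seed, miR-200b, miR-200c and miR-429 together went from 4.16% to 6.25% (1.5) and miR-200a and miR-141 together from 2.52% to 2.78% (1.11). The 5p arms of the family held 0.0532% of reads in the uninduced control, 0.0625% in the induced pool and 0.0315% in the set 1 control. Their DKO ratio to control was 0.0627 (0.0248 to 0.132; 7 reads against 167) in set 2. In set 1 it was 0.261 (0.0684 to 0.709), on 4 reads against 51, a smaller fall than that of the whole family.

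**Figure D1:**
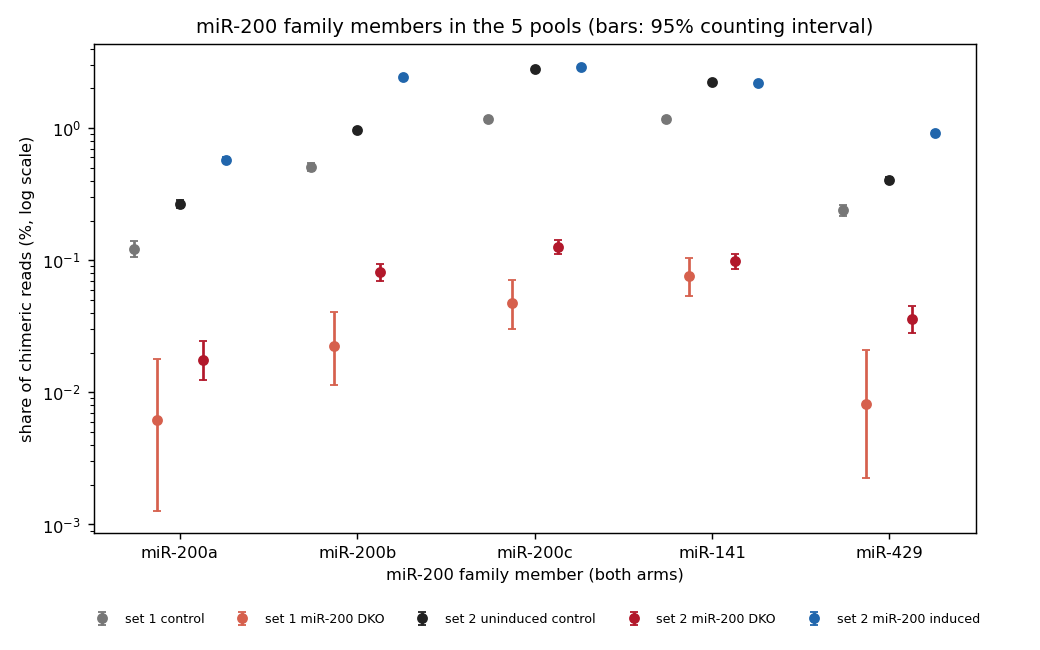
Share of chimeric reads of each miR-200 family member in the 5 pools, on a log scale with 95% counting intervals. The DKO pools lie far below the controls for every member, and the induced pool lies above the uninduced control for miR-200a, miR-200b and miR-429.

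Outside the family, the miRNAs of the paired miR-23, miR-27 and miR-24 clusters and the epithelial miR-205 held a larger share in both DKO pools than in control. miR-27a-3p went from 2.76% to 3.98% in set 1 (ratio 1.45, 1.37 to 1.52) and from 4.03% to 7.95% in set 2 (1.97, 1.93 to 2.02). miR-23a-3p went from 2.40% to 3.90% and from 3.21% to 5.82% (1.62 and 1.81). miR-24-3p went from 1.46% to 2.14% and from 1.49% to 3.08% (1.46 and 2.06) and miR-205-5p from 2.57% to 3.55% and from 2.56% to 5.39% (1.38 and 2.10). miR-27b-3p (1.61 and 3.03) and miR-23b-3p (1.37 and 3.47) were higher too. Grouped after their values were seen, the 6 together held 10.3% and 15.2% in set 1 and 12.6% and 26.4% in set 2. miR-23a and miR-23b, like miR-27a and miR-27b, are near-identical in sequence, so the division within each pair is less certain than its sum. Also higher in both DKO pools were miR-342-3p (3.39, 2.24 to 5.13, and 1.28, 1.03 to 1.59), miR-140-3p (1.38 and 2.48) and miR-466c-5p (1.98 and 1.55). Lower in both was miR-155-5p, known from activated immune cells (1 read against 54 in set 1, ratio 0.0615, 0.00153 to 0.358, and 7 against 85 in set 2, ratio 0.123, 0.0481 to 0.265). So was miR-298-5p (0.637 and 0.635). Of the 291 miRNAs with at least 20 reads in both DKO comparisons, 33 were higher in both (25.9 if the sets were independent), 2 were lower in both (13.4) and 52 went opposite ways (37.4). With at least 50 reads 28 were higher in both (27.8 if independent), so an excess of shared rises was not seen there. With at least a 2-fold ratio, 3 were higher (3.5) and 1 lower (2.4) in both; without 9 miRNAs overrepresented in set 1, 6 were lower in both and the set 1 interval of miR-140-3p included 1 (0.882 to 1.61).

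Within set 1, 84 of 556 miRNAs were higher in the DKO pool and 108 lower by their counting intervals. Within set 2, 106 of 363 were higher and 86 lower. The balance depended on the counting. In set 1, 65 were higher and 149 lower without the 9 miRNAs, and 73 and 64 with each position counted once. In set 2, 91 were higher and 97 lower when shares were taken among miRNAs outside the family. These many calls go with wide scatter: among miRNAs with at least 500 reads, the log2 ratio had an SD of 0.84 over 59 miRNAs in set 1 and 0.68 over 107 in set 2, and 9 and 12 of them differed at least 2-fold. Their median ratio was 1.27 in set 1 (1.16 without these 9 miRNAs) and 1.02 in set 2. The 6 miRNAs together thus stood at 1.16 times the median in set 1 and 2.06 times the median in set 2. Several of the most abundant keratinocyte miRNAs had different ratios in the 2 sets. miR-31-5p held 4.07% and 4.97% in set 1 control and DKO (1.22) and 11.0% and 8.12% in set 2 (0.735). miR-21a-5p held 2.49% and 3.19% (1.28) and 8.44% and 7.67% (0.909); with each position counted once its set 2 ratio was 1.02 (1.00 to 1.05), on the same side of 1 as in set 1. miR-125b-5p held 0.952% and 1.03% (1.08, 0.975 to 1.2) and 4.56% and 2.36% (0.517, 0.500 to 0.534). The set 1 control was led instead by miR-709 (12.4% and 12.5%), miR-3470b (6.46% and 3.53%, ratio 0.547) and miR-706 (4.80% and 4.46%, ratio 0.929), each given for control and DKO; in the set 1 DKO pool miR-31-5p came next after miR-709. These held 1.08%, 0.405% and 0.470% of the set 2 control (DKO ratios 0.890, 1.29 and 1.55). miR-709 depended on the counting: with each position counted once it held 2.82% of the set 1 control, and without reads shared within the lane its set 1 DKO ratio was 0.600 (0.576 to 0.626) in place of 1.01. Together with 6 further names these miRNAs made up 37.5% of the set 1 control, 27.7% of the set 1 DKO pool and 3.46%, 4.29% and 3.63% of the set 2 uninduced, DKO and induced pools. With these 9 left out of the total, the set 1 ratio of the abundant miRNAs was smaller: 1.06 (1.01 to 1.11) for miR-31-5p, 1.25 for miR-27a-3p, 1.19 for miR-205-5p and 1.28 for the 6 miRNAs together.

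Some further miRNAs were chosen after their values were seen because 1 set moved more than the other. In set 2, the DKO share over control was 0.337 for miR-29a-3p, 0.378 for miR-29b-3p, 0.321 for miR-193a-3p and 0.311 for miR-365-3p, against 0.880, 0.989, 1.38 and 0.990 in set 1, and it was 6.53 (5.31 to 8.11) for miR-196a-5p against 0.992. In set 1, miR-467a-5p (6.66, 5.75 to 7.72), miR-669a-5p (5.46) and miR-203-3p, a miRNA of differentiating epidermis (2.98, 2.72 to 3.27), were higher in the DKO pool, against 0.864, 1.01 and 0.800 in set 2. The sensory and epithelial cluster of miR-182-5p, miR-183-5p and miR-96-5p stood at 0.692, 0.660 and 0.530 in set 2 and at 1.27, 1.1 and 1.2 in set 1, where without the 9 miRNAs all 3 intervals included 1. miR-16-5p (1.66 and 1.32) and let-7b-5p (1.79 and 1.36) were higher in both.

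**Figure D2:**
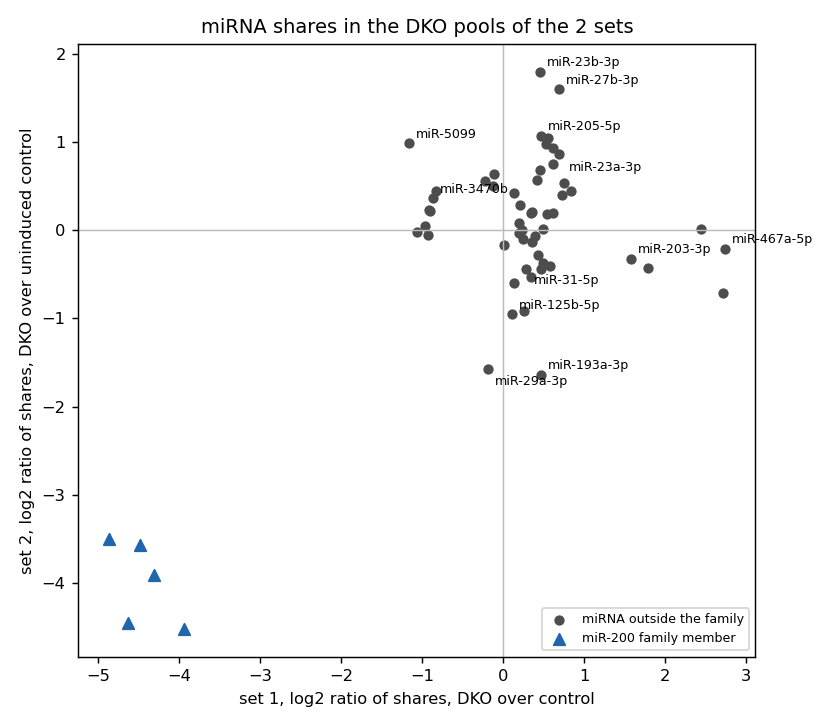
Log2 ratio of the share in DKO over control for 54 miRNAs outside the family with at least 500 reads in both sets, with the 5 family members as triangles. The family lies far below 0 on both axes, and the other miRNAs scatter around medians of 0.38 in set 1 and 0.13 in set 2, with miR-27b-3p and miR-23b-3p higher in both sets.

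Doxycycline for 24 hours left most other miRNAs near their uninduced share. Over 119 miRNAs with at least 500 reads the log2 ratio of induced over uninduced had an SD of 0.13, and 0 of them differed 2-fold. miR-31-5p (1.03), miR-21a-5p (0.946), miR-27a-3p (0.951), miR-23a-3p (0.954), miR-24-3p (1.01) and miR-125b-5p (0.968) lay within that spread, while miR-205-5p was at 0.873 (0.847 to 0.900), miR-706 at 1.24 (1.16 to 1.32) and miR-3470b at 1.14 (1.06 to 1.22). Of 412 miRNAs, 28 were higher and 44 lower by their counting intervals. With shares taken among miRNAs outside the family, 37 were higher and 34 lower. The largest ratios were those of rare miRNAs: miR-7053-3p 2.17 (1.29 to 3.81; 58 reads against 20), the neuronal miR-132-3p 1.84 (1.07 to 3.26), miR-712-3p 1.78, miR-218-5p 1.78 and miR-676-3p 1.64 were higher. Of the rest, miR-187-3p 0.477 (0.262 to 0.849), miR-6984-3p 0.504, miR-203-5p 0.528 (0.381 to 0.730), miR-15a-3p 0.562 and miR-30e-3p 0.606 were lower. miR-203-3p, chosen after its values were seen, went from 1.38% to 0.970% (0.701, 0.672 to 0.732), in the same direction as its 5p arm. The labels give no doxycycline-treated cells without the inducible construct, so the drug and the induction were not separated. With at least a 2-fold ratio 6 miRNAs were higher and 6 lower, and with each position counted once 14 were higher.

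The fixed miRNA lists show the same picture by group. The epidermal list (miR-31, miR-21a, miR-205 and others) held 19.6% and 27.8% in set 1 control and DKO (ratio 1.42). Of its 17 measured names 11 were higher and 0 lower. In set 2 it held 39.8% and 47.3% (1.19, with 10 names higher and 7 lower). Without the 9 miRNAs the ratios were 1.224 and 1.198 (1.188 to 1.208), nearer each other. The list includes miR-23a, miR-23b, miR-27a, miR-27b, miR-24 and miR-205, so its ratio is not separate from theirs. Of its other members, miR-31-5p (0.735) and miR-125b-5p (0.517) were lower in the set 2 DKO pool. The let-7 family (1.45 and 0.990), the miR-17-92 group (1.32 and 1.11), the miR-34 family (1.53 and 1.11) and the miR-15 and miR-16 group (1.53 and 1.25) were nearer control in set 2; without the 9 miRNAs their set 1 ratios were 1.25, 1.14, 1.32 and 1.32. The miR-183 cluster (1.18 and 0.626) and the miR-29 and miR-30 group (1.1 and 0.645) went opposite ways in the 2 sets; without the 9 miRNAs their set 1 ratios were 1.02 (0.95 to 1.09) and 0.953 (0.888 to 1.02). Induced over uninduced, these 7 lists stood between 0.916 (miR-183 cluster) and 1.04 (miR-34).

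miRNAs of other cell types were rare in every pool. The mesenchymal list (miR-143, miR-145a, miR-199 and miR-214) held 0.116% of the set 1 control and 0.0349% of the set 1 DKO pool (0.300, 0.171 to 0.494) and 0.00796%, 0.0129% and 0.0134% of the set 2 pools (DKO 1.62, 0.902 to 2.90; induced 1.68, 1.03 to 2.81). The muscle (0.309), blood (0.302) and embryonic (0.466) lists were lower in the set 1 DKO pool by similar factors, and their set 2 ratios of 1.37, 1.12 and 0.914 had intervals that included 1. The endothelial list, which was miR-126a alone, held 0.0490% of the set 2 control (DKO 0.505, 0.361 to 0.696; induced 1.06) and 8 and 5 reads in set 1 (2.08, 0.535 to 7.20). The neural list (miR-124, miR-128, miR-138 and miR-9) was at 2.18 (1.72 to 2.77) in the set 2 DKO pool and 1.38 (0.861 to 2.15) in set 1, and the liver miRNA miR-122 had 1 to 3 reads in each pool. Induced over uninduced, the muscle, blood, embryonic and neural lists were at 1.56, 1.12, 1.33 and 0.980 with intervals that included 1.

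The transcripts to which miR-200 was ligated were many, and none dominated. The family had at least 2 distinct chimeras on 901 genes in the set 1 control (4850 chimeras), on 2775 in the uninduced control (19114) and on 3981 in the induced pool (34261); the 10 leading genes held 4.52%, 4.30% and 4.04% of chimeras. Mitochondrial targets, counted but not named, took 1.90%, 2.42% and 2.40% of miR-200 chimeras in the set 1 control, uninduced and induced pools. Among named genes, first came the nuclear noncoding RNA Neat1, the scaffold of paraspeckles, with 0.701%, 1.39% and 1.39% in these pools. Then came the giant scaffold protein gene Ahnak (0.619%, 0.460% and 0.379%), the noncoding RNA Malat1 (0.412%, 0.445% and 0.458%), the fatty acid desaturase Scd2 (0.351%, 0.356% and 0.403%) and Tnrc6a, which encodes a partner of Argonaute in silencing (0.268%, 0.403% and 0.295%). Next were the lipoprotein receptor Vldlr (0.454%, 0.204% and 0.216%), the anticoagulant receptor thrombomodulin Thbd (0.433%, 0.173% and 0.198%), Rbms1 and the annexin Anxa1. Foxp1, Efna5, the desmosomal gene Perp, Grip1, the chromatin protein gene Hmga2, the vesicle coat gene Sec23a, the polarity gene Pard3, the splicing factor Mbnl1 and the growth factor Nrg1 each held between 0.168% and 0.222% on average. Ext1 (0.392%, 0.0837% and 0.0817%) and Dlc1 (0.433%, 0.268 to 0.661, against 0.0628%, 0.0324 to 0.110, and 0.0496%) took a larger part of the set 1 chimeras. Between induced and uninduced pools the ratio had an interval excluding 1 for the following genes named by rule: Tnrc6a (0.732, 0.539 to 0.998), Grip1 (0.671, 0.469 to 0.965), Marcks (0.513, 0.278 to 0.942), Trp63 (0.452, 0.224 to 0.899) and Cdh2 (15 chimeras against 1, ratio 8.37, 1.29 to 352). These intervals were not adjusted for the number of genes named, so some may exclude 1 through counting error alone. Genes were assigned by their whole span, introns included, and a long gene gathers chimeras over all of it. The order is by number of miR-200 chimeras and does not show preference over other miRNAs. In the uninduced pool Neat1 had 266 miR-200 chimeras and 3756 of other miRNAs, Malat1 85 and 991 and Hmga2 37 and 745. By contrast, Vldlr had 39 and 64, Sec23a 38 and 38 and Dlc1 12 and 15. All chimeras of that pool numbered 19114 and 239795.

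**Figure D3:**
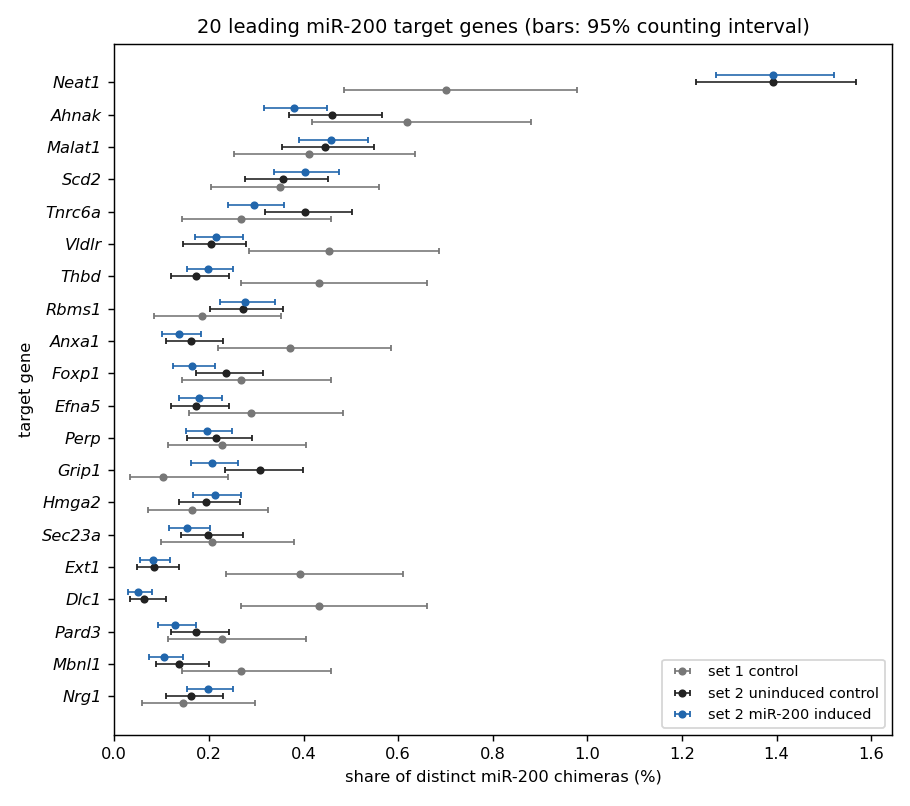
Share of distinct miR-200 chimeras on the 20 leading target genes in the 3 pools that kept the family, with 95% counting intervals. Neat1 leads in all 3 pools, and Dlc1 and Ext1 are higher in the set 1 control than in set 2.

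On many leading genes the chimeras stacked at 1 place. Overlapping targets formed 35937 sites, of which 1242 held at least 5 chimeras (28.1% of 58225), 163 held at least 20 and 607 were seen in all 3 pools. Sites in mitochondrial and structured RNA are not named here. A mitochondrial site (298 to 1005) held 268 chimeras in the uninduced and 479 in the induced pool without reads shared within the lane. The other counts of this paragraph keep such reads, so a molecule found in several pools of a set counts in each. With them the deepest Scd2 site held 39 chimeras in the uninduced and 95 in the induced pool, and without them 33 and 88. The deepest site in Scd2 (chromosome 19, 44303236 to 44303357) had 146 chimeras. Of these Scd2 chimeras, 99.3% had the seed of miR-200b, miR-200c and miR-429 (96.2 to 100). Sites of that kind also lay in Vldlr (chromosome 19, 27249355 to 27249439; 119 chimeras, 99.2%), Tnrc6a (chromosome 7, 123194279 to 123194363; 102, 99.0%), Ahnak (81, 96.3%), Anxa1 (74, 93.2%), Sec23a (64, 100%), the desmosomal cadherin Dsg3 (48, 95.8%), the RNA-binding gene Qk (45, 100%) and Ago2 (24, 100%). The leading sites of Thbd (chromosome 2, 148405286 to 148405506; 84 chimeras, 3.66%, 0.761 to 10.3) and Perp (chromosome 10, 18855978 to 18856071; 52, 1.92%, 0.0487 to 10.3) carried almost only miR-200a and miR-141. Mbnl1 (46, 52.2%) and Neat1 (55, 70.9%) took both seeds. In Dlc1 35 of its 50 chimeras lay on 1 site, 19 of them from the set 1 control, whereas in Grip1 the deepest site held 7 of 135, in Hmga2 5 of 118 and in Ext1 7 of 63.

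**Figure D4:**
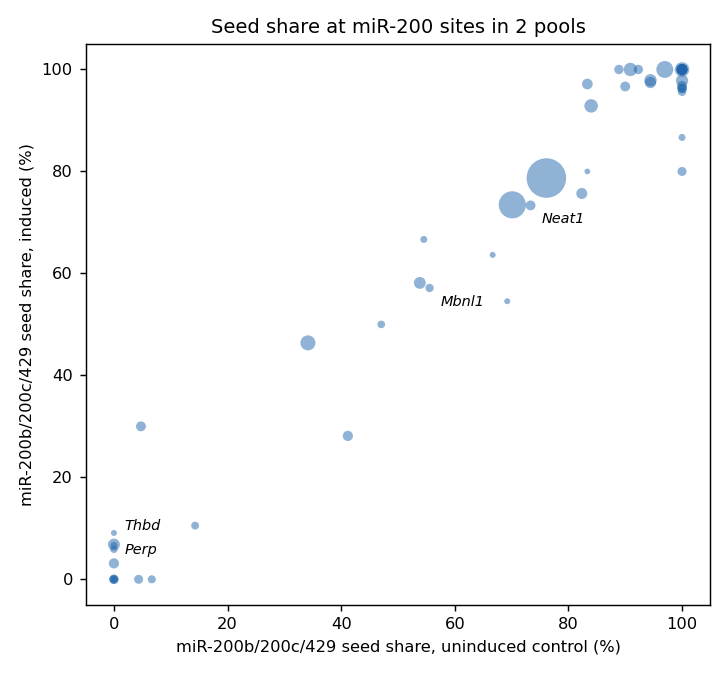
Percent of miR-200 chimeras that carry the miR-200b, miR-200c and miR-429 seed at each of 79 sites with at least 10 chimeras in both the uninduced and the induced pool; point size follows the induced count. Reads shared within the lane were left out, and mitochondrial and structured RNA sites are included. Sites gather near 0 and near 100 and hold their place between pools, with Thbd and Perp near 0 and Neat1 and Mbnl1 between.

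The target genes recurred between pools. The set 1 and set 2 controls shared 717 genes where independence would give 264.0 and 10000 draws weighted by the chimeras of other miRNAs gave a median of 505 and at most 558. The set 1 control and the induced pool shared 798 (363.3 by independence, at most 672 in draws). The uninduced and induced pools shared 2324 (1003 and at most 1861). In each comparison 0 of 10000 draws were as large. In the DKO pools 4 genes (set 1) and 68 genes (set 2) had at least 2 miR-200 chimeras, and Neat1 led in set 2 with 17 of 750; 2 and 5 genes were left without the reads shared within the lane.

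Among fixed gene lists, commonly cited miR-200 targets were the most enriched against chimeras of other miRNAs in the same pool when distinct chimeras were counted. With every read counted, the small RNA machinery list stood higher in set 2 (3.15 against 2.53 uninduced and 2.25 against 2.21 induced). By distinct chimeras, the commonly cited targets took 1.54%, 1.22% and 1.15% of miR-200 chimeras assigned to genes in the set 1 control, uninduced and induced pools. This is 3.16, 2.43 and 2.23 times their part of other chimeras (Fisher exact test on chimeras, adjusted p = 9.88e-14, 1.56e-25 and 8.15e-35 over 13 lists). Dlc1 gave 21 of the 68 set 1 chimeras, while in the induced pool Msn had 58, Sec23a 53, Cfl2 46 and Qk 45. The best-known pair of the list, the transcription factors Zeb1 and Zeb2 that drive epithelial-mesenchymal transition, were chosen after their values were seen and had 1 and 0 miR-200 chimeras over these 3 pools, and 1 and 4 chimeras of other miRNAs. The list of small RNA machinery was at 1.59 (adjusted exact p = 0.193), 2.00 (3.93e-10) and 1.46 (4.12e-05), led by Tnrc6a (13 of 23, 77 of 121 and 101 of 173 chimeras) and Ago2 (2, 17 and 29), with Dicer1 at 3, 5 and 10. Without Tnrc6a, an alternative chosen after the values were seen, this list was at 0.987 (adjusted exact p = 1), 1.09 (0.923) and 0.883 (0.563), so its enrichment rested on 1 gene. The cited targets without the leading gene of each pool (Dlc1, Sec23a and Msn) were at 2.27, 2.07 and 2.24 (adjusted exact p = 1.85e-05, 5.29e-15 and 1.77e-29). The tests compare chimeras within a pool, which are not independent samples of cells, and do not compare conditions.

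The basal keratinocyte list (Perp, Trp63, Itga6) was at 1.87 (adjusted exact p = 0.0189), 1.19 (0.141) and 1.17 (0.124), and 11 of its 29 set 1 chimeras lay on Perp, without which the list was at 1.42 (0.818), 0.888 (0.721) and 0.831 (0.230). Lists with fewer miR-200 chimeras in set 2 than other miRNAs gave were the differentiated keratinocyte list (Notch2, Krt6a, Klf4), at 1.07 (adjusted exact p = 1), 0.536 (0.000645) and 0.411 (6.33e-08), and cell and focal adhesion (Dsg3, Actn1, Itgav), at 0.854 (0.585), 0.737 (4.96e-05) and 0.815 (0.000279). The cell cycle list (Cdk6, E2f3, Cdkn1b) was at 0.856 (1), 0.708 (0.0367) and 0.780 (0.0325), and the Wnt and hair follicle list (Bmpr1a, Lrp6, Fgfr2) at 1.13 (1), 0.649 (0.0165) and 0.980 (1). EMT regulators and mesenchymal genes (Smad2, Cdh1, Cdh2) were at 0.574 (0.525), 1.16 (0.467) and 1.07 (0.893) with 6, 46 and 83 chimeras. In the uninduced pool, the Wnt and hair follicle list no longer passed the test without a leading gene of that list. The fibroblast, melanocyte, immune and endothelial lists had 0 to 2 miR-200 chimeras in each pool.

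Most targets lay in protein-coding genes: 85.4%, 82.8%, 83.4%, 83.3% and 84.5% of distinct chimeras of all miRNAs in the set 1 control, set 1 DKO, set 2 uninduced, set 2 DKO and induced pools, and 87.0%, 85.9% and 86.6% of miR-200 chimeras in the 3 pools that kept the family. Counting every read lowered the first 5 values to 76.3%, 74.0%, 75.4%, 77.4% and 77.0%. Noncoding RNA genes such as Neat1 and Malat1 took 2.70% to 3.46% and mitochondrial transcripts 1.30% to 3.68% of all chimeras; with every read counted, mitochondrial transcripts took 2.02% and 3.58% in set 1 and 9.01%, 7.58% and 8.99% in the uninduced, DKO and induced pools of set 2. In 5355 long genes with 1 clear strand, the last 10% of the span, where the 3' UTR commonly lies, held 33.0%, 33.4% and 33.7% of miR-200 chimeras in the set 1 control, uninduced and induced pools, against 17.7%, 28.7% and 28.9% of those of all miRNAs outside the family, and 23.2%, 29.3% and 29.5% with the 9 set 1 miRNAs left out. miR-709 and the 8 other miRNAs overrepresented in set 1 placed 3.26% to 4.77% of their chimeras there.

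For miRNAs outside the family, some keratinocyte transcripts held a larger share of reads in both DKO pools, though no more genes than independence would give. Anxa1 stood at 3.35 (2.22 to 5.07) in set 1 and 1.61 (1.30 to 2.00) in set 2, the basal keratin Krt14 at 2.61 (1.61 to 4.20) and 2.06 (1.65 to 2.57). Suco, on which 41.6% of reads were those of miR-27a-3p, was at 1.65 and 3.09. The Notch ligand Jag1 was at 2.12 and 1.90 and the repressor Klf3 at 2.08 and 1.87. Lower in both were Ccbe1 (0.174, 0.0780 to 0.338, and 0.107, 0.0501 to 0.203), the matrix protein gene Sparc (0.460 and 0.0990), on which 53.2% of reads were those of miR-29a-3p, Phldb2 (3 reads against 48, ratio 0.201, 0.0401 to 0.625, and 0.385) and the noncoding genes LOC115490435 (0.203 and 0.0626) and Gm52861 (0.322 and 0.0743). Most reads on the last pair were of miR-709 (98.9% and 98.4%), and with each position counted once their set 1 ratios were 1.49 (0.704 to 3.01) and 1.24 (0.343 to 3.79). By counting intervals 169 genes were higher and 208 lower of 2110 in set 1, and 645 and 559 of 4350 in set 2. Of 671 genes compared in both sets 14 were higher in both (16.5 by independence) and 23 lower (20.7), close to what the separate counts give. A ratio here follows the transcript, its miRNAs and the ligation together.

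In the induced pool other miRNAs were found more on Lrrc32 (3.12, 2.12 to 4.72), D5Ertd615e (2.84, 1.61 to 5.28), Gk5 (2.63), Nfx1 (2.56) and the transcription factor gene Nfya (2.36). They were found less on Tab3 (0.320, 0.163 to 0.600), the miRNA genes Mir23a (0.323) and Mir16-1 (0.344) and the cornified envelope genes Sprr1b (0.331, 0.210 to 0.511) and Sprr1a (0.384, 0.222 to 0.647). The Sprr pair was higher in the set 1 DKO pool (Sprr1b 5.13, 3.10 to 8.63, and Sprr1a 3.60, 1.77 to 7.37). In the set 2 DKO pool both intervals included 1 (Sprr1b 0.681, 0.441 to 1.03, and Sprr1a 1.37, 0.888 to 2.11). Of 5091 genes 218 were higher and 190 lower. In simulated data with counting error alone, 3.35% of unchanged genes were called in this comparison. Over genes with at least 500 reads the log2 ratio had an SD of 0.21 (75 genes; 0.20 with each position counted once), against 0.90 (39 genes; 0.64) in the set 2 DKO comparison; in set 1 only 8 genes had that many reads.

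The 10 pairs of a miRNA outside the family and a gene with the highest mean share over the 5 pools are given here. They included miR-709 with Gm34755 (0.478% of reads), Sltm (0.307%), LOC115490435 (0.182%), Gm35818 (0.0988%), Gm39056 (0.0904%) and Morc1 (0.0712%), each at 10 to 39 positions. These means lean on set 1, where miR-709 held 12.4% of control reads against 1.08% in set 2. In the set 2 uninduced pool miR-21a-5p on Mir21a (437 reads) and miR-31-5p with Neat1 (378) exceeded each miR-709 pair, of which Sltm had most (337). miR-31-5p with Neat1 (0.0856%, 918 positions) and with the tight junction gene Cldn4 (0.0780%, 450 positions) spread over many. miR-21a-5p on its own gene Mir21a (0.167%) and miR-7068-5p on Mir7068 (0.0713%) pair a miRNA with the locus it comes from.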

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

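Of the tests here, those of the number of positions under the 9 set 1 miRNAs, of the loss of miR-200 reads from the total, of the DKO miR-200 reads not shared within the lane, the totals without the 9 miRNAs and the medians of abundant miRNAs were chosen only after results were seen.

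The miR-200 reads left in the DKO pools drew attention because barcodes recurred between pools. At positions with 1 read in each of 2 pools, the barcodes were equal in 69.7% of cases between the set 1 control and DKO pools, 58.7% between the set 2 uninduced and DKO pools, 52.0% between uninduced and induced and 66.6% between DKO and induced, against 0.0903% to 0.488% between pools of different sets. DKO miR-200 reads were shared in this way 3.92 times (set 1) and 9.18 times (set 2) as often as reads of other miRNAs, which argues against separate molecules from cells that kept the loci as the source of most of them; reads carried over between libraries of a lane may be the source. Each member's DKO reads in set 2 were 1.11% to 1.47% of its control and induced reads together, and 2.94% to 5.90% of its control reads alone; in set 1 they were 1.04% to 1.88% of its control reads. What stays open are the 25 and 72 reads not found in another pool: at a ratio to control of 0.0186 in set 1, carry-over of a molecule unseen elsewhere and a small number of cells with intact loci cannot be told apart, since the counts are few and no library is named.

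A second pattern is the excess of miR-709 and 8 other miRNAs in set 1, where they held 10.8 times their set 2 control share. Targets under 30 bases that map by chance are argued against, as the ratio was 10.8 without them (10.6 to 11.1). This covers the length of the target part alone. Wrong mapping of longer targets and the naming of the miRNA part were not tested. A few crowded positions are argued against as the source of this excess: the 10 most frequent held 4.28% of these reads in the set 1 control. With each position counted once the ratio was 11.8. In the other pools the 10 most frequent held more, 10.9% in the set 1 DKO pool and 9.27% to 13.2% in set 2. For miR-709 alone crowding did matter to the share, which was 12.4% of the set 1 control by reads and 2.82% by positions. Its ratio to the set 2 control by positions was still 9.84 (9.09 to 10.7). Their reads per position (1.87 against 1.19 for other miRNAs) and their part outside annotated genes (23.7% against 5.95%) were high. The control cells of the sets differ in genotype and were sequenced in separate runs, so genotype, culture, library preparation and run stay open as untested explanations.

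The third pattern is the larger share of miR-23a, miR-23b, miR-27a, miR-27b, miR-24 and miR-205 in both DKO pools. These 6 were grouped after their ratios were seen, so their sum is no separate support. Other abundant miRNAs, such as miR-31-5p (0.735) and miR-125b-5p (0.517), were lower in the set 2 DKO pool. The removal of miR-200 reads from the total accounts for little of the larger share of the 6 miRNAs. The family held 3.20% and 6.68% of control reads, so leaving it out could change the ratios only slightly. Among miRNAs outside the family the ratio was 1.43 in set 1 (at least 1.39 by its interval) and 1.97 in set 2. With the shares already known, these values could not have come out otherwise. A few crowded positions are argued against, with 1.36 and 2.03 when each position counted once. The set 1 value is open to the 9 miRNAs, without which it was 1.28 (1.24 to 1.31), to a general rise, since abundant miRNAs had a median ratio of 1.27 and the 6 stood at 1.16 times that median (2.06 times in set 2), and to the scatter between pools, which has no replicate to measure it. A difference in these miRNAs between DKO and control keratinocytes may remain as a hypothesis. Different clones, passage or preparation of the cells were not tested. The set 1 control was K14-Cre only, while the set 2 control was miR-200 inducible cells without doxycycline, so the sets do not repeat the same contrast. An effect of the inducible construct on the set 2 ratios was not tested.

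Further results stand out because the DKO ratio lay above 1 in 1 set and below 1 in the other; with 1 pool per group the differences were not tested, and values are the set 1 ratio over the set 2 ratio. miR-467a-5p was at 7.70, miR-193a-3p at 4.31, miR-203-5p at 4.02 and miR-203-3p at 3.73. miR-96-5p was at 2.26, miR-182-5p at 1.84, miR-31-5p at 1.66 and miR-21a-5p at 1.41, and without the 9 miRNAs at 1.94, 1.57, 1.42 and 1.21. With each position counted once, miR-21a-5p had ratios above 1 in both sets (1.31 and 1.02). miR-3470b was at 0.425 and miR-706 at 0.599; without reads shared within the lane the set 1 ratio of miR-706 was 1.00 (0.956 to 1.06).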

How the results depend on the processing

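Alternatives without reads shared within the lane, without marked read names, without the 9 set 1 miRNAs, without the leading gene of each gene list (over the 3 pools, or in each pool) or with at least a 2-fold ratio were chosen after the data were seen; the others were planned. Over all results and alternatives 1077 values stayed within their interval or count range, 228 moved, 25 reversed, 7 passed the test no longer without the leading gene of a list (among them small RNA machinery and Wnt and hair follicle in the uninduced pool, basal keratinocyte in the set 1 control) and 2 passed the test only when every read counted (basal keratinocyte in the induced pool, small RNA machinery in the set 1 control). No paired analysis was possible because the files pool the libraries of a group, and leaving out each replicate and count models with replicates were not possible for the same reason. Seed match alternatives and UTR before coding order were not run, for want of genome sequence and exons. In simulated data the set 1 DKO comparison, the shallowest, recovered fewer 2-fold changes than those of set 2, so a miRNA or gene without a call in set 1 was not shown to be unchanged. Where values below moved, the cause was not tested, except that totals without reads of other miRNAs raise the family's shares and stricter minimums lower counts by construction.

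With each position counted once the family's share was 4.13% (set 1 control), 0.206% (set 1 DKO), 7.38% (uninduced), 0.413% (set 2 DKO) and 9.90% (induced). Lower miRNAs in set 1 numbered 64, higher miRNAs on induction 14 and lower target genes in set 1 121. Reversed were the set 1 ratios of Gm52861 (1.24) and LOC115490435 (1.49), the set 2 DKO ratios of miR-21a-5p (1.02) and miR-709 (1.04) and the difference between sets of miR-709 (0.968). With every read counted, protein-coding genes held 76.3%, 74.0%, 75.4%, 77.4% and 77.0% of targets in the set 1 control, set 1 DKO, uninduced, set 2 DKO and induced pools, and 84.7% and 85.7% of miR-200 targets in the uninduced and induced pools.

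With the guide arm alone the family held 3.31%, 6.83% and 9.23% in the set 1 control, uninduced and induced pools. Without the most abundant miRNA of each pool it held 3.65%, 7.50% and 10.2% there and 0.391% in the set 2 DKO pool. Without structured RNA, mitochondrial and miRNA gene targets it held 7.22%, 0.386% and 9.76% in the uninduced, DKO and induced pools of set 2. Without marked names the set 1 control was at 3.31%.

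Without reads shared within the lane the family held 3.34%, 0.0622%, 6.99%, 0.0382% and 9.46% in the set 1 control, set 1 DKO, uninduced, set 2 DKO and induced pools, with DKO ratios of 0.0186 and 0.00546 and a ratio of these of 3.41 (2.16 to 5.38). The difference between sets reversed for miR-200b (3.48) and miR-709 (0.730), the set 1 ratio of miR-706 was 1.00 (0.956 to 1.06), and 2 and 5 genes kept at least 2 miR-200 chimeras in the DKO pools.

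Without the 9 set 1 miRNAs the family held 5.13%, 0.222%, 6.92% and 9.38% in the set 1 control, set 1 DKO, uninduced and induced pools, 6 miRNAs were lower in both DKO pools, and the miR-29 and miR-30 list in set 1 reversed to 0.953. Without the leading gene of each gene list, chosen either way, ratios fell below 1 for small RNA machinery (0.987 in the set 1 control, 0.883 induced), basal keratinocyte (0.888 uninduced, 0.831 induced), EMT regulators (0.958 uninduced, 0.968 induced), differentiated keratinocyte (0.932, set 1 control) and Wnt and hair follicle (0.786, set 1 control).

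With at least a 2-fold ratio, 36 miRNAs were higher in set 1, 42 higher and 33 lower in set 2 DKO, 6 higher and 6 lower on induction, and 3 higher and 1 lower in both DKO comparisons; target genes numbered 398 and 366 in set 2 DKO and 89 and 71 on induction. With at least 50 reads, 62 miRNAs were lower in set 1, and target genes numbered 63 higher and 117 lower in set 1, 398 higher in set 2 DKO and 143 higher on induction. With at least 3 chimeras, about 4.3e+02 genes were miR-200 targets in the set 1 control, 0 in the set 1 DKO and 12 in the set 2 DKO pool, and the set 1 control shared 362 genes with the uninduced and 393 with the induced pool. With at least 1 chimera the pools shared 1711 and 1881 genes with the set 1 control, and 3756 were shared between uninduced and induced pools.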

Other observations

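The tests of seed preference and of take-over were set before their results were seen; the list shares over all miRNAs, the omission of reads shared within the lane and the inclusion of the 9 set 1 miRNAs were chosen after.

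Over all miRNAs, the gene lists divided the pools in other ways than miR-200 did. Differentiated keratinocyte genes held 0.169% of chimeric reads in the set 1 control and 0.403% in the set 1 DKO pool (0.348 to 0.463), against 0.271% and 0.262% in set 2 and 0.203% (0.189 to 0.217) on induction; the miR-203-3p share stood at 0.617% and 1.84%, 1.38% and 1.11%, and 0.970% in the same pools. Basal keratinocyte genes such as Krt14 held 0.271% and 0.360% in set 1 and 0.439% and 0.541% in set 2, with 0.371% on induction. Cell cycle genes held 0.296% and 0.440% in set 1 and 0.318% and 0.414% in set 2. Adhesion genes were at 1.15% and 1.1%, and 1.24% and 1.03%. Fibroblast, immune and endothelial genes stayed at 12 reads or fewer in each pool and melanocyte genes at 21 or fewer.

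Sites of miR-200 may prefer 1 of its seeds. Over sites with enough chimeras, the variance of the seed share was compared with what 1 fixed proportion gives. It was 11.2 times as large in the uninduced pool (97 sites) and 13.1 times in the induced pool (236 sites). For miR-200b against miR-200c, which share a seed, it was 2.62 (61 sites) and 2.90 (134 sites). The first is 4.28 and 4.50 times the other, so 1 fixed proportion of the seeds over sites is argued against. This measure grows with the chimeras per site and the contrasts use different sites, so these factors do not give the size of a preference. In the uninduced pool 58 of 97 sites carried over 90% and 15 under 10% of the miR-200b, miR-200c and miR-429 seed. For the part of miR-200b against miR-200c, 0 of 61 sites lay over 90% and 9 under 10%. The seed shares of 79 sites ranked alike in the uninduced and induced pools with reads shared within the lane left out (Spearman correlation = 0.880 across sites, which are not independent replicates). Whether the preferred sites hold the matching sequence was not analysed here.

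A further hypothesis was that other miRNAs take over miR-200 sites when miR-200 is absent. With the 9 set 1 miRNAs left out, the share of other miRNAs' chimeras on miR-200 sites was 1.33 times control in the set 1 DKO pool (1.26 to 1.41). It was 0.935 times control in the set 2 DKO pool (0.916 to 0.955) and 0.910 times on induction (0.893 to 0.927). A rise in both DKO pools was thus not seen. With the 9 included these values were 1.51, 0.934 and 0.907. The sites were defined from the pools that kept miR-200, which favours those pools. Without the 9, the part of other miRNAs' chimeras at the ends of long genes, where miR-200 chimeras were more frequent, also moved. It was 23.2% in control and 30.6% in DKO in set 1. In set 2 it was 29.3% uninduced, 25.9% in DKO and 29.5% induced. The DKO ratios on sites cannot separate a take-over from this shift, so they do not decide the hypothesis.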
